A study of Homo sapiens with 8 samples.

How the data were processed

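RNA from 8 cultures of human multiple myeloma cells was measured on 8 Affymetrix arrays, 1 for each cell line and treatment. The established lines RPMI-8226 and JJN3 each gave 4 cultures: uninfected cells, cells given a lentivirus with a non-targeting (NT) shRNA, cells given a lentivirus with an shRNA against XBP1, and cells given a lentivirus with an shRNA against IRE1, the protein encoded by ERN1. Per the labels, infection lasted 16 h with 8 µg/mL polybrene, and the cultures were harvested at 96 h. The 2 lines served as the replicates of each treatment (n = 2), RPMI-8226 as replicate 1 and JJN3 as replicate 2. Arrays are named by line and by the treatment on their label.

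Per the submitters' processing notes the signals were processed with RMA, a method that returns background-adjusted, quantile-normalised probe set values; the notes give no software version. The deposited values were taken as log2 units, because RMA returns that scale; the notes state neither the log base nor any centring. In the table of 54675 probe sets by 8 arrays, each of the 54675 probe sets had a median of 0 over the 8 arrays (tolerance 1e-05), and the values ran from -5.73 to 5.45. The centred values give differences between arrays but no expression level and no signal over background. The number of arrays limits the precision. No pair of the 28 array pairs was identical (0 pairs). Percentages of a control level assume base 2.

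Probe sets were named from the array annotation. A single symbol was given for 41097 probe sets, covering 19775 genes; 1801 probe sets had several symbols and 11777 were not listed. Entrez identifiers of 41043 of the named probe sets matched the reference gene table (assembly GRCh38.p14, used for names only), 54 did not, and 0 symbols were updated. The choices of test, filter, gene lists, named genes and alternatives were made before the data were examined, apart from those stated here as made later. A gene was to be tested if its probe set reached the median of the table in at least 2 arrays, which on centred values removed 0 probe sets. A gene with several probe sets (10523 genes; 9252 had 1) was to be represented by the probe set of highest mean. Because means of centred values say nothing of intensity, the probe set with the highest SD over the 8 arrays was used instead, a choice made after the centring was seen; the original rule was run as an alternative.

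Differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, all tests two-sided), with p adjusted by the Benjamini-Hochberg method over the 19775 genes and a threshold of 0.05. The fit for XBP1 shRNA against NT shRNA, IRE1 shRNA against NT shRNA, IRE1 shRNA against XBP1 shRNA and NT shRNA against uninfected used all 8 arrays, 4 treatments and the cell line as a block. Silenced (XBP1 or IRE1 shRNA) against control (NT shRNA or uninfected) was a fit of 4 arrays against 4 with the same block. The interaction compared the silencing effect of JJN3 with that of RPMI-8226. In it the 2 shRNAs and the 2 controls of a line stood as its replicates, so its spread is that between unlike treatments. A last fit compared JJN3 with RPMI-8226 with treatment as the block. Errors are standard errors (SE) of these fits. Genes that differed at least 2-fold the same way in both lines were counted without a test. Log2 differences were also correlated across genes between comparisons that share no array; genes are not independent replicates, so no p was computed.

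The gene lists were 25 in number, with 573 genes, of which 516 were measured: XBP1-dependent secretory pathway, endoplasmic reticulum (ER) chaperones and disulfide enzymes, N-glycosylation, ER-to-Golgi transport, PERK-ATF4 stress genes, reported IRE1 RNase decay targets, plasma cell identity, B cell and plasmablast genes, MHC class II, immunoglobulin genes, interferon response, NF-kB targets, proteasome, S phase, G2 and mitosis, MYC and ribosome biogenesis, p53 targets, BCL2 family and apoptosis, heat shock proteins, cholesterol and fatty acid synthesis, hypoxia and glycolysis, and markers of T and NK cells, of myeloid cells, of stromal and epithelial cells, and of erythroid cells. A few genes, such as JCHAIN and CIITA, stand on more than 1 list, and myeloma cells themselves express some markers of the other cell types, VIM among them. Lists were tested with camera (limma), which compares a list with all other genes, at a preset correlation of 0.01 and adjusted over the lists of a comparison. They were tested again with a correlation estimated from the data, and with fry (limma), whose test asks whether the genes of a list move, on balance, in 1 direction and compares them with no other genes. Within a line, list medians were ranked among 10000 random lists matched on SD (seed 20). The design named mean expression for this matching, which centred values do not hold. Members were also adjusted over the list alone.

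The named genes of a comparison were the 12 with the largest positive and the 12 with the largest negative log2 difference among genes past the threshold with the same sign in both lines. Where fewer than 6 passed in a direction, the list was filled to 10 with genes that did not pass, ranked by the smaller of the per-line differences; these are given as values. XBP1 and ERN1 were always named, and members of a list could be named beside it. Probe sets of immunoglobulin and HLA genes can cross-hybridise with related genes.

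The alternatives were a filter at the 60th percentile of probe set means, the mean of a gene's probe sets, all probe sets without collapsing, an intensity trend with robust variances, quantile and cyclic loess normalisation of the deposited values, no replicate block, a threshold of 0.1, other control arrays, a fold of 1.5, fry, an estimated correlation and each array left out in turn. On centred values the percentile filter, the trend and the loess curve follow the mean of centred values, not intensity. With an array left out, its treatment stands in 1 line and its lone array is assumed to vary like the others. Added after seeing the data were the filter to probe sets above the median SD (quantile 0.5), the probe set of highest mean, and 3 settings of the list tests. The fits were tested on simulated data of 19775 genes and 10 runs for XBP1 shRNA against NT shRNA, with 200 changed genes per run. There, 19.0% of genes with a log2 change of 0.585, 92.2% of those with 1 and 100% of those with 2 were found, and 8.14% of the calls were false. The changes were placed on the XBP1 shRNA arrays, and comparisons without a simulated difference of their own were fitted in the same runs. Their mean number of calls was 0.9 for IRE1 shRNA against NT shRNA, 1.1 for NT shRNA against uninfected and 0.1 for the interaction. The changed arrays also enter the spread of the interaction. A list shifted by -0.7 was found in 10 of the 10 runs with the preset and in 9 with the estimated correlation. The simulated genes varied independently of each other, so these runs say nothing of lists whose genes move together. All probe sets of a changed gene were given the same change. The share found therefore does not cover genes whose probe sets disagree. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Probe sets with several symbols or none were left out of the gene comparisons because they name no gene.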

Results

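The data collected were 8 arrays of 54675 probe sets, 4 from RPMI-8226 and 4 from JJN3, both myeloma lines grown from malignant human plasma cells. Each line gave 1 array of uninfected cells, 1 with NT shRNA, 1 with XBP1 shRNA and 1 with IRE1 shRNA. IRE1 is the ER stress sensor whose RNase splices the mRNA of XBP1, a transcription factor that drives secretory pathway genes in plasma cells. Correlations between the centred arrays of a line, across probe sets, lay between 0.725 and 0.873 in RPMI-8226 and between 0.735 and 0.897 in JJN3. Because the values are centred over both lines, these correlations also hold the difference between the lines. They do not measure reproducibility. The poly-A control transcripts added to the RNA (24 probe sets) had their highest median on the XBP1 shRNA array in both lines, 0.43 in RPMI-8226 and 0.19 in JJN3. The next highest were the NT shRNA arrays, at 0.25 and -0.05. The 3' minus 5' difference of actin, a sign of RNA integrity, was taken from the centred values. Only its differences between arrays can be read, not its sign. It ran from -0.61 to -0.43 in RPMI-8226. In JJN3 it ran from 0.13 to 0.42 and so moved with the line. That of GAPDH overlapped between the lines, at -0.083 to 0.062 in RPMI-8226 and 0.0037 to 0.046 in JJN3. A difference in RNA integrity between the lines therefore cannot be read from actin alone. In both lines the actin difference was lowest on the NT shRNA array (-0.61 and 0.13), the control of the shRNA comparisons.

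The first question was whether each shRNA lowered its target. XBP1 (200670_at) on the arrays labelled XBP1 shRNA stood at 65.9% of the NT shRNA array in RPMI-8226 and at 45.6% in JJN3. On the arrays labelled IRE1 shRNA it stood at 64.7% and 16.8%. ERN1 (235745_at), the gene of IRE1, stood at 36.7% and 42.9% on the arrays labelled XBP1 shRNA, and at 129.8% in RPMI-8226 and 53.9% in JJN3 on the arrays labelled IRE1 shRNA. In the limma fit XBP1 differed from NT shRNA by -0.87 ± 0.38 with XBP1 shRNA (adjusted p = 0.314 over all genes and 0.0492 over the targets alone) and by -1.60 ± 0.38 with IRE1 shRNA (0.181 and 0.00460). ERN1 differed by -1.33 ± 0.33 with XBP1 shRNA (0.0771 and 0.00555) and by -0.26 ± 0.33 with IRE1 shRNA (0.876 and 0.453). Against uninfected cells ERN1 fell by 1.88 on the log2 scale with XBP1 shRNA (adjusted p = 0.0226) and differed by -0.80 with IRE1 shRNA (0.589). Between the shRNAs, IRE1 minus XBP1, the difference was -0.73 for XBP1 (adjusted p = 0.414; 0.11 without the JJN3 IRE1 shRNA array) and 1.08 for ERN1 (0.124). ERN1 on the NT shRNA array differed from uninfected cells by -1.02 in RPMI-8226 and by -0.06 in JJN3. For ERN1, 227755_at gave differences like those of 235745_at, -1.36 and -1.38 with XBP1 shRNA, and 0.23 and -1.16 with IRE1 shRNA, in RPMI-8226 and JJN3. For IRE1 shRNA the sign for ERN1 turned to 0.07 without the JJN3 NT shRNA array and to 0.26 without the JJN3 IRE1 shRNA array; it was 0.0636 after cyclic loess and 0.0093 with 207061_at. With 207061_at ERN1 was at -0.0746 with XBP1 shRNA (-0.14 in RPMI-8226 and -0.0137 in JJN3). For XBP1, 242021_at gave -0.0834 with XBP1 shRNA (-0.20 in RPMI-8226 and 0.0324 in JJN3) and turned the sign with IRE1 shRNA, to 0.0478. XBP1 with XBP1 shRNA was -1.32 without the RPMI-8226 NT shRNA array and -0.41 without the JJN3 NT shRNA array.

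**Figure D1:**
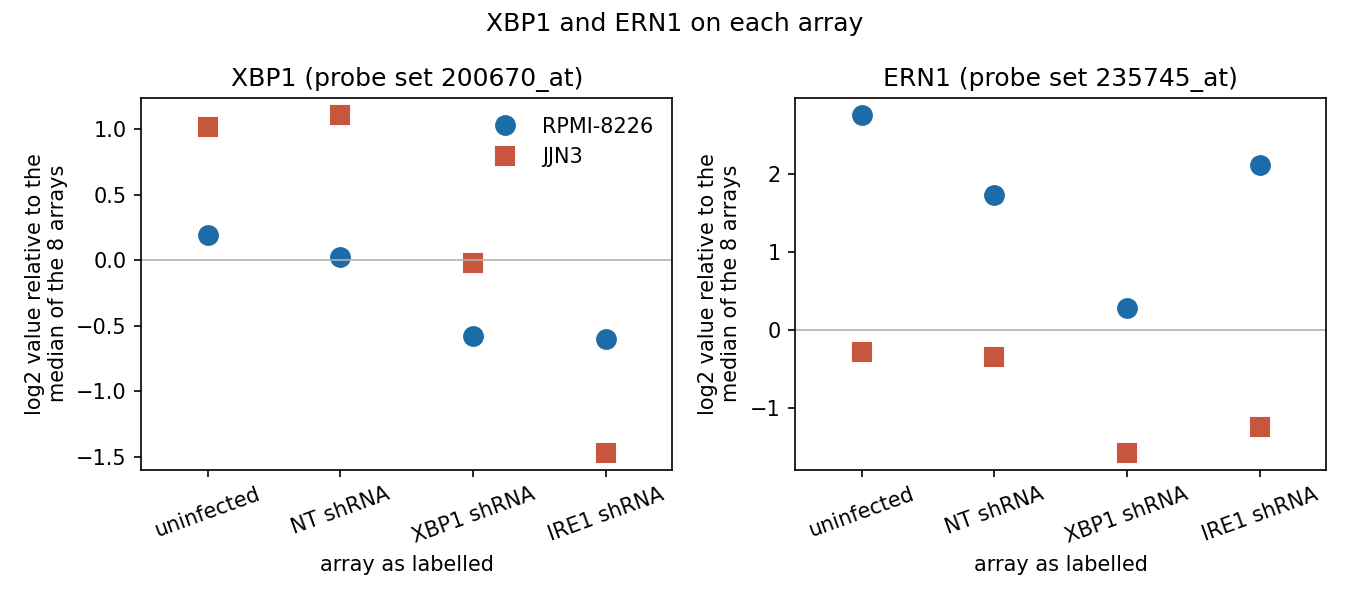
Values of XBP1 and ERN1 on each of the 8 arrays (vertical axis, deposited log2 values centred on each probe set's median; horizontal axis, treatment on the label; 1 point per line). XBP1 was lowest at -1.47 on the JJN3 IRE1 shRNA array, and ERN1 was lowest at -1.57 on the JJN3 XBP1 shRNA array.

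XBP1 shRNA against NT shRNA asked what changes when XBP1 is targeted. Single genes of the secretory and plasma cell identity lists fell, 2 of 39 and 2 of 20 over all genes (1 and 1 after quantile normalisation). DNAJB9, an ER co-chaperone, fell by 1.25 ± 0.20 on the log2 scale and SSR2, a subunit of the translocon-associated complex, fell by 0.81. PRDM1 and IRF4, transcription factors that set plasma cell identity, fell by 1.23 and 1.06, and DDIT3, the stress transcription factor CHOP, fell by 1.17. Over all genes 190 genes rose and 246 fell, 436 in all, each with the same sign in both lines (limma; 3130 genes had an unadjusted p under 0.05, where chance gives about 989). Such agreement in sign, here and in the comparisons below, is near certain in a fit whose replicates are the lines. It is no separate evidence. The median size of the 436 changes was 1.02 on the log2 scale. Among the largest falls were EIF4EBP1, a repressor of translation initiation (-2.41 ± 0.31), MPI, an enzyme of mannose metabolism (-2.28), HMGA1, a chromatin architectural protein (-2.13 ± 0.16), MARCKSL1, an actin-binding protein (-2.06 ± 0.16), and the mitochondrial carrier UCP2 (-1.84). WDR41, TEX14, PLBD2, XXYLT1, TOX2, TMEM132D-AS1 and DYNLT1 fell as well, from -1.93 for WDR41 to -1.70 for DYNLT1. Among the largest rises were DCP2, the mRNA decapping enzyme (2.07 ± 0.17), RPRD1A, an RNA polymerase II regulator (1.96), RAC1 (1.78 ± 0.33), EEA1, an early endosome tether (1.69), and the histone genes H2BC21 (1.62) and H2AC8 (1.56). STXBP4, ZNF596, LIPT2-AS1, PLEKHA3, ATP1B1 and SPACA9 rose by between 1.58 and 1.66. RAC1 had differed by -1.72 between NT shRNA and uninfected cells. The choice of probe set mattered: with another choice 12 of these 24 genes shrank by more than 1.5 times. With the probe set of highest mean DCP2 was at -0.63, PLBD2 at 0.12, WDR41 at -0.0181, HMGA1 at -0.38, RAC1 at 0.0359 and SPACA9 at 0.0256, and with the mean of its probe sets RPRD1A was at -0.21. RAC1 lost its call in 12 of 20 alternatives. The poly-A control median of the XBP1 shRNA arrays was 0.43 in RPMI-8226 and 0.19 in JJN3, against 0.25 and -0.05 on the NT shRNA arrays.

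By list, 9 of the 25 shifted in this comparison with camera. Of the 29 PERK-ATF4 stress genes 1 fell over all genes (DDIT3) and 10 fell adjusted over the list alone. Its members had a median of -0.77 (-0.50 in RPMI-8226, -1.05 in JJN3; adjusted p = 4.60e-08, and adjusted p = 0.820 with an estimated correlation). Its largest differences were SARS1, seryl-tRNA synthetase (-1.56), SESN2 (-1.39) and PCK2, mitochondrial phosphoenolpyruvate carboxykinase (-1.34). Of 39 XBP1-dependent secretory genes 2 fell over all genes and 12 adjusted over the list alone, HERPUD1, an ER-associated degradation factor (-0.88), and SEC61B, a translocon subunit (-0.82), among the latter. The list median was -0.25 (adjusted p = 6.73e-05, and adjusted p = 0.380 with an estimated correlation). Of 20 plasma cell identity genes 2 fell over all genes and 5 adjusted over the list alone, with MZB1, an ER protein of antibody-secreting cells, at -0.85. The median of the list was -0.46 (adjusted p = 0.000271; adjusted p = 0.380 with an estimated correlation). Of 19 ER chaperones MANF fell by 0.83, and 3 fell adjusted over the list alone; UGGT1, the glucosyltransferase that senses misfolded glycoproteins, was at -0.84, and the list median was -0.18 (adjusted p = 0.00522; adjusted p = 0.380 with an estimated correlation). Of 31 ER-to-Golgi genes the GTPase ARF4 and the SNARE BET1 fell by 1.14 and 0.89 and the COPII coat gene SEC23A rose by 0.81; adjusted over the list alone 2 rose and 7 fell. The list median was -0.13 (adjusted p = 0.0364; adjusted p = 0.841 with an estimated correlation). The median of the 26 N-glycosylation genes was -0.19 (0.0364, with an estimated correlation adjusted p = 0.419), that of the 12 MHC class II genes -0.26 (0.0320; adjusted p = 0.841 with an estimated correlation) and that of the 20 MYC and ribosome biogenesis genes -0.31 (0.00206; adjusted p = 0.820 with an estimated correlation), the last with SRM, spermidine synthase, at -0.97 and MYC at -0.75. The 31 G2 and mitosis genes had a median of 0.31, 0.54 in RPMI-8226 and 0.07 in JJN3 (adjusted p = 8.03e-05; adjusted p = 0.820 with an estimated correlation), with the proliferation marker MKI67 at 1.01. Within lists that did not shift, the proteasome subunits PSMB2 and PSMD11 rose by 0.85 and 0.77, the caspase inhibitor XIAP and the cell death factor BAD rose by 1.18 and 0.74, the p53 target ZMAT3 rose by 1.28, and CDH1, E-cadherin, fell by 1.25.

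The other 16 lists did not shift: the camera adjusted p was 0.0854 for S phase, 0.120 for stromal and epithelial markers, 0.266 for NF-kB targets, 0.386 for the proteasome, 0.463 for interferon response and for p53 targets, 0.532 for hypoxia and glycolysis and 0.602 for cholesterol synthesis. It was 0.613 for erythroid markers, 0.676 for heat shock proteins, 0.678 for T and NK markers, 0.766 for myeloid markers, for the BCL2 family and for the reported IRE1 RNase decay targets, 0.914 for immunoglobulin genes and 0.972 for B cell genes. The median of the heat shock list was -0.07 and its mean 0.07. Some of these lists had opposite signs in the lines, which the joint fit averages. S phase medians were 0.25 in RPMI-8226 and -0.50 in JJN3, and those of the BCL2 family -0.19 and 0.28. The count of 436 was 0 without the RPMI-8226 NT shRNA array (2307 at an unadjusted p under 0.05), 36 without the JJN3 NT shRNA array, 192 without either uninfected array, 201 without either IRE1 shRNA array and 224 without the RPMI-8226 XBP1 shRNA array, and was 0 without the cell line block (381 at an unadjusted p under 0.05). The balance of rises and falls turned on single arrays: 126 rose and 98 fell without RPMI-8226 XBP1 shRNA, and 105 and 245 without JJN3 XBP1 shRNA. List calls ended without single arrays: ER chaperones without JJN3 NT shRNA (adjusted p = 0.0850); ER-to-Golgi without JJN3 NT shRNA (0.403), RPMI-8226 XBP1 shRNA (0.401) or either uninfected array (0.0513). N-glycosylation ended without RPMI-8226 XBP1 shRNA (0.132), JJN3 NT shRNA (0.113), JJN3 XBP1 shRNA (0.0938), RPMI-8226 NT shRNA (0.0560) or either uninfected array (0.0513). MHC class II ended without JJN3 XBP1 shRNA (0.658) or RPMI-8226 NT shRNA (0.532). G2 and mitosis ended without RPMI-8226 XBP1 shRNA (0.261), and MYC without JJN3 XBP1 shRNA (0.208) or JJN3 NT shRNA (0.113). Against uninfected cells the calls of N-glycosylation (median -0.0407, adjusted p = 0.235) and ER-to-Golgi (-0.0800, 0.116) ended, and the medians were -0.14 for XBP1-dependent secretory genes, -0.55 for MHC class II, -0.19 for MYC and 0.19 for G2 and mitosis. Among calls that held, without RPMI-8226 NT shRNA the medians were -1.19 for PERK-ATF4, -0.25 for plasma cell identity, 0.14 for G2 and mitosis, -0.30 for ER chaperones and -0.23 for ER-to-Golgi. Without JJN3 NT shRNA they were -0.39 for PERK-ATF4 and -0.46 for MHC class II, and without RPMI-8226 XBP1 shRNA -0.45 for MHC class II. Without JJN3 XBP1 shRNA they were -0.27 for plasma cell identity, 0.51 for G2 and mitosis, -0.29 for ER chaperones and -0.25 for ER-to-Golgi.

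IRE1 shRNA against NT shRNA asked the same of the sensor. Few single genes passed: H2BC12, a histone gene, fell by 2.25 ± 0.20 on the log2 scale (adjusted p = 0.0243), MACROD1, an ADP-ribose hydrolase, fell by 1.95, RPIA, an enzyme of the pentose phosphate pathway, fell by 1.54, and the ubiquitin ligases RNF149 and RNF11 fell by 1.48 and 1.25. MOSPD1, FBXO45, MREG and NTAQ1 fell by 1.57, 1.35, 1.30 and 1.26. SSBP3, a transcription cofactor, rose by 1.43 ± 0.17 (adjusted p = 0.0372), DCP2, the decapping enzyme, by 1.41 (0.0433), and TMED4, a cargo receptor of the early secretory pathway, by 1.37 (0.0372). That made 3 genes that rose and 9 that fell, 12 in all, each with the same sign in both lines; 2090 genes had an unadjusted p under 0.05, and the median size of the 12 changes was 1.42. SSBP3 had differed by -1.25 between NT shRNA and uninfected cells. Next in the upward direction, not past the threshold, came RAC1 (1.85), CMAHP (1.5), MRPL43 (1.34), KLHL5 (1.34), NUP35 (1.24), SP2-AS1 (1.23) and CDCA3 (1.14).

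In this comparison the secretory and stress lists again had negative medians and MHC class II genes positive ones. Of 39 XBP1-dependent secretory genes 0 passed over all genes and 19 fell adjusted over the list alone, DNAJC3, the PERK inhibitor p58IPK (-1.17), DNAJB9 (-0.97), SSR2 (-0.89) and SEC61B (-0.86) among them. The median of the list was -0.44 (-0.27 in RPMI-8226, -0.46 in JJN3; adjusted p = 2.28e-11, and adjusted p = 0.342 with an estimated correlation). Of 29 PERK-ATF4 genes 11 fell adjusted over the list alone, with SESN2 at -1.70, the cystine transporter SLC7A11 at -1.60 and DDIT3 at -1.42. The list median was -1.06, from -0.14 in RPMI-8226 and -1.85 in JJN3 (adjusted p = 4.33e-15; adjusted p = 0.419 with an estimated correlation). The hybridisation control median of the JJN3 IRE1 shRNA array was 0.42, where the other JJN3 arrays lay between -0.0047 and 0.0479. All 12 of the 12 MHC class II genes, which present antigen and whose probe sets can cross-hybridise, had positive differences, and HLA-DPB1 (0.87), the invariant chain CD74 (0.71) and HLA-DRA (0.59) rose adjusted over the list alone. The median of the list was 0.55, from 0.22 in RPMI-8226 and 1.06 in JJN3 (adjusted p = 1.85e-05; adjusted p = 0.419 with an estimated correlation). Against uninfected cells it was 0.21 (0.19 and 0.32; adjusted p = 0.0299), and NT shRNA minus uninfected had medians of -0.0828 and -0.58 for this list. Of 31 G2 and mitosis genes DLGAP5 (0.73), the kinesins CENPE (0.73) and KIF11 (0.68) rose adjusted over the list alone, and the median was 0.35 (adjusted p = 5.29e-07; adjusted p = 0.419 with an estimated correlation). Of 31 ER-to-Golgi genes SEC22B (-0.99), BET1 (-0.67) and the coatomer gene ARCN1 (-0.61) fell adjusted over the list alone, and the median was -0.21 (adjusted p = 0.000204; adjusted p = 0.419 with an estimated correlation). ER chaperones (median -0.27, adjusted p = 0.000851, and adjusted p = 0.342 with an estimated correlation), the BCL2 family (-0.18, 0.00467), N-glycosylation (-0.11, 0.0189) and cholesterol synthesis (-0.20, 0.0211) also shifted down, the last 3 with adjusted p = 0.419 with an estimated correlation. PMAIP1, the cell death factor NOXA, was at -1.08, and HMGCS1 and INSIG1, of the sterol pathway, were at -1.08 and -0.85. Heat shock proteins did not pass (0.0533). In the proteasome list, which did not shift (0.499), 4 genes rose and 2 fell adjusted over the list alone, PSMD11 at 0.93.

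The count of 12 was 0 without the RPMI-8226 NT shRNA array, either uninfected array or the JJN3 IRE1 shRNA array, 2 without JJN3 NT shRNA, 31 without either XBP1 shRNA array and 32 without RPMI-8226 IRE1 shRNA; it was 0 without the cell line block. At these counts of 0, in the order given, limma had 1469, 1967, 953 and 180 genes at an unadjusted p under 0.05. List calls ended without JJN3 NT shRNA for ER chaperones (adjusted p = 0.0527), N-glycosylation (0.0639) and cholesterol synthesis (0.0527), and without JJN3 IRE1 shRNA for N-glycosylation (0.104), ER-to-Golgi (0.0813) and cholesterol synthesis (0.266). They ended without RPMI-8226 NT shRNA for the BCL2 family (0.252) and cholesterol synthesis (0.0631), and without RPMI-8226 IRE1 shRNA for the BCL2 family (0.0718). Against uninfected cells the calls of the BCL2 family (median -0.0796, adjusted p = 0.133; 0.0046 in RPMI-8226 and -0.0394 in JJN3), N-glycosylation (-0.0493, 0.155) and cholesterol synthesis (0.0663, 0.102) ended, and the median of XBP1-dependent secretory genes was -0.28. Against NT shRNA the BCL2 family medians were -0.21 in RPMI-8226 and -0.0308 in JJN3. With another choice of probe set 5 of the 12 genes shrank by more than 1.5 times. With that of highest mean DCP2 was at -0.0209, TMED4 at -0.49, SSBP3 at 0.17, MACROD1 at -0.33 and MOSPD1 at -0.95. Among calls that held, without JJN3 IRE1 shRNA the medians were -0.34 for PERK-ATF4, -0.27 for XBP1-dependent secretory genes, -0.11 for ER chaperones and 0.32 for MHC class II. Without RPMI-8226 IRE1 shRNA they were -1.74 for PERK-ATF4, 0.94 for MHC class II, -0.32 for ER-to-Golgi and -0.17 for N-glycosylation. Without JJN3 NT shRNA they were -0.61 for PERK-ATF4, 0.25 for MHC class II and -0.28 for the BCL2 family. Without RPMI-8226 NT shRNA that of G2 and mitosis was 0.19.

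**Figure D2:**
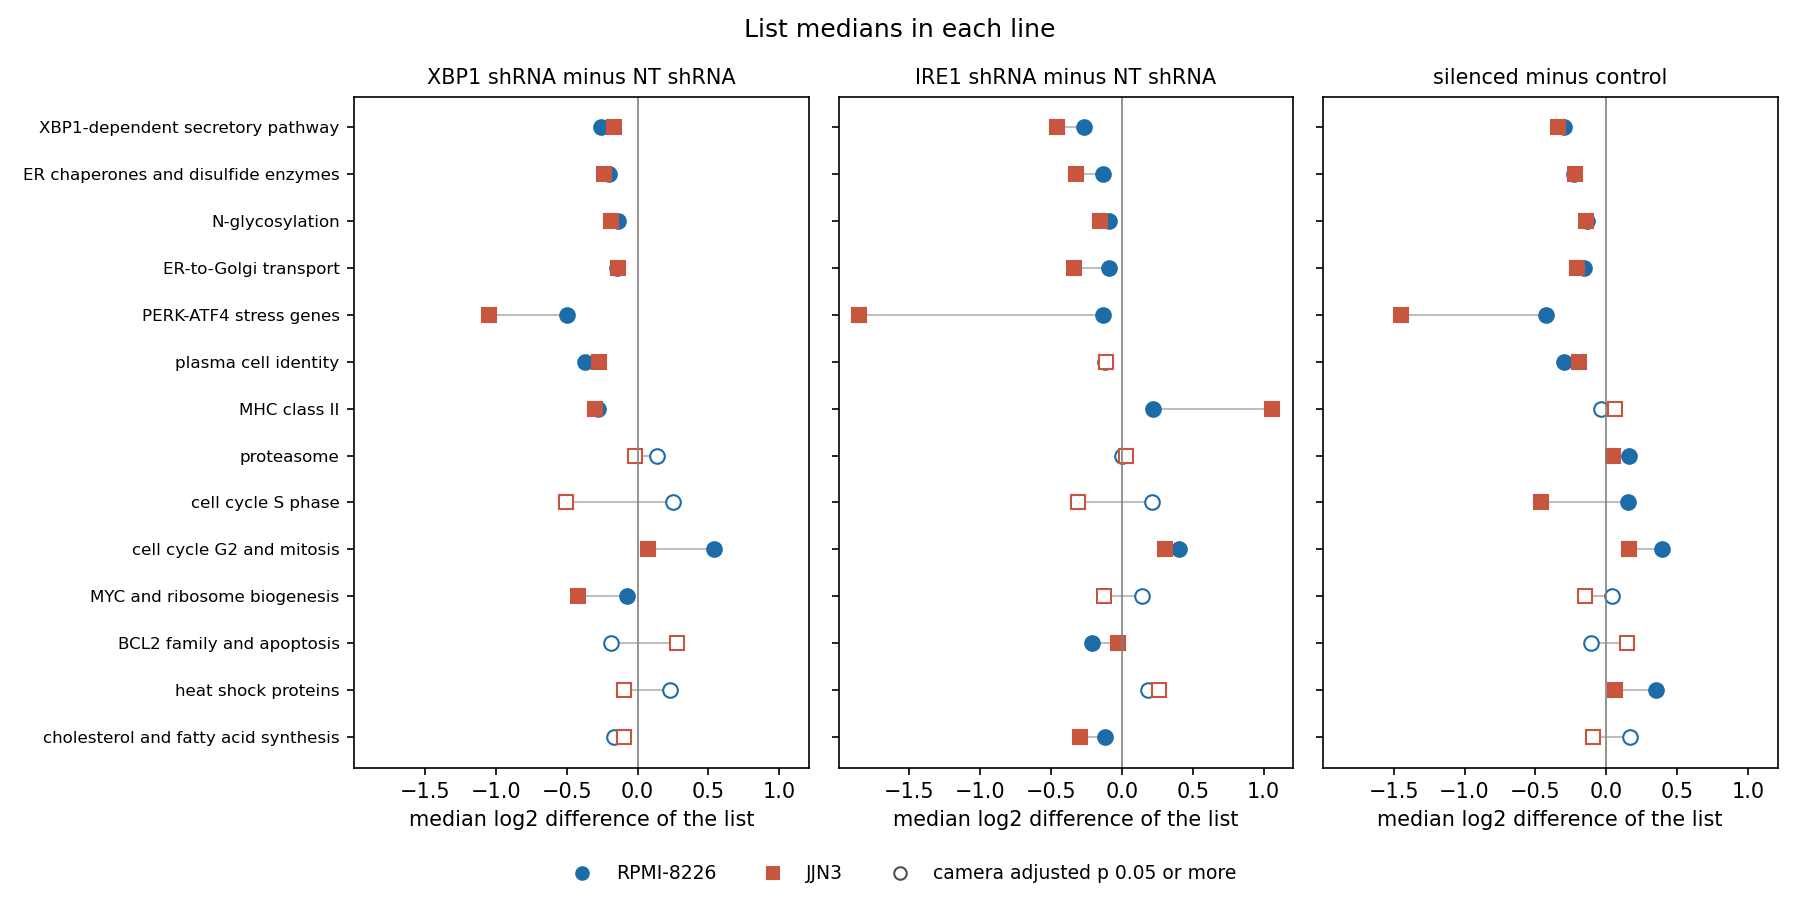
Median log2 difference of the genes of 14 lists (horizontal axis) in each line for XBP1 shRNA minus NT shRNA, IRE1 shRNA minus NT shRNA and silenced minus control, 1 mark per line; open marks are lists whose camera adjusted p was 0.05 or more. The PERK-ATF4 median was -1.85 in JJN3 and -0.14 in RPMI-8226 for IRE1 shRNA minus NT shRNA.

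Silenced against control arrays compared both shRNAs with both controls. The list with the lowest camera p at the preset correlation was the PERK-ATF4 stress genes, which serve amino acid supply, tRNA charging and the response to unfolded proteins. Adjusted over the list alone 25 of 29 fell, and 27 were lower in both lines. PCK2 (-1.57 ± 0.29), SESN2 (-1.49 ± 0.31), ALDH1L2, of mitochondrial folate metabolism (-1.48 ± 0.31), SARS1 (-1.41 ± 0.25) and DDIT3 (-1.17 ± 0.18) were among those that fell. The list median was -1.02, with -0.42 in RPMI-8226 and -1.45 in JJN3 (adjusted p = 1.29e-24; adjusted p = 0.181 with an estimated correlation; fry adjusted p = 0.0920). Of 39 XBP1-dependent secretory genes 10 fell adjusted over the list alone, DNAJB9 (-1.01), HERPUD1 (-0.91) and SSR2 (-0.72) among them, and the list median was -0.35 (adjusted p = 1.74e-11; adjusted p = 0.0602 with an estimated correlation; fry adjusted p = 0.0148). Of 19 ER chaperones MANF fell adjusted over the list alone (-0.58), and the median was -0.21 (adjusted p = 5.82e-05; adjusted p = 0.0602 with an estimated correlation; fry adjusted p = 0.00539). Of 20 plasma cell identity genes the transcription factor CREB3L2 (-0.95) and MZB1 (-0.72) fell adjusted over the list alone, with a median of -0.29 (adjusted p = 0.000471; adjusted p = 0.181 with an estimated correlation). In ER-to-Golgi transport SEC22B (-0.84), BET1 (-0.78) and TMED2 (-0.42) fell and SEC23A (0.53) rose adjusted over the list alone, with a median of -0.19 (adjusted p = 0.000236; adjusted p = 0.282 with an estimated correlation). Of the N-glycosylation genes ALG2, a mannosyltransferase, fell adjusted over the list alone (-0.54), with a median of -0.09 (adjusted p = 0.0113; adjusted p = 0.181 with an estimated correlation). G2 and mitosis genes had a median of 0.28 (adjusted p = 3.68e-08; adjusted p = 0.277 with an estimated correlation). S phase genes shifted down, with medians of 0.15 in RPMI-8226 and -0.46 in JJN3 (adjusted p = 0.00799; adjusted p = 0.790 with an estimated correlation), and CDC6, a replication licensing factor, fell adjusted over the list alone (-0.59). Heat shock proteins (0.17, adjusted p = 0.0232; adjusted p = 0.320 with an estimated correlation) and the proteasome (0.12, 0.0232; adjusted p = 0.643 with an estimated correlation), in which PSMD11 rose adjusted over the list alone (0.81), shifted up. Neither list had passed for an shRNA against NT shRNA, and NT shRNA minus uninfected had medians of 0.34 and 0.12 for heat shock proteins and 0.18 and 0.0277 for the proteasome, in RPMI-8226 and JJN3. The 9 reported IRE1 RNase decay targets had a median of 0.07 (adjusted p = 0.405), with the complement regulator CD59 at 0.42 and TGOLN2 at 0.21.

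No single gene passed over all genes in this comparison: limma called 0 genes, with 1992 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0669. Named by their size in both lines, INHBE, an activin subunit, was at -2.60 (adjusted p = 0.208), EIF4EBP1 at -1.71, RAB39B at -1.64, IL21R at -1.35, MPI at -1.21, ADCY1 at -1.20, SLC35F6 at -1.16, REPS2 at -1.13 and GLMP at -1.08. DCP2 was at 1.61 (0.0669), PLEKHA1 at 1.08, PLEKHA3 at 1.06, PRPF38A at 1.03, MRPL43 at 1.02, YOD1 at 0.97, EEA1 at 0.91, TPM1 at 0.89, SPOPL at 0.87 and SERTAD2 at 0.85; with the probe set of highest mean DCP2 was at -0.22 and ADCY1 at 0.0288. XBP1 was at -1.25 ± 0.31 (adjusted p = 0.223) and ERN1 at -1.07 ± 0.36 (0.349). The count was 40 without the RPMI-8226 IRE1 shRNA array and 2 without RPMI-8226 uninfected; with NT shRNA as the sole control it was 25, 12 higher and 13 lower. Single arrays ended the proteasome call (adjusted p = 0.324 without RPMI-8226 uninfected, 0.158 without RPMI-8226 XBP1 shRNA), the S phase call (0.343 without JJN3 uninfected, 0.513 without JJN3 XBP1 shRNA) and the heat shock call (0.145 without RPMI-8226 uninfected, 0.154 without RPMI-8226 IRE1 shRNA). Among list calls that held, ER-to-Golgi had medians of -0.11 without JJN3 NT shRNA and -0.0952 without JJN3 IRE1 shRNA, plasma cell identity -0.19 without RPMI-8226 XBP1 shRNA, and N-glycosylation -0.15 without RPMI-8226 uninfected. S phase had -0.20 without RPMI-8226 NT shRNA or RPMI-8226 XBP1 shRNA and -0.21 without RPMI-8226 IRE1 shRNA, and heat shock proteins 0.33 without JJN3 XBP1 shRNA and 0.0829 without JJN3 IRE1 shRNA. Without the cell line block limma called 0 genes (332 at an unadjusted p under 0.05).

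**Figure D3:**
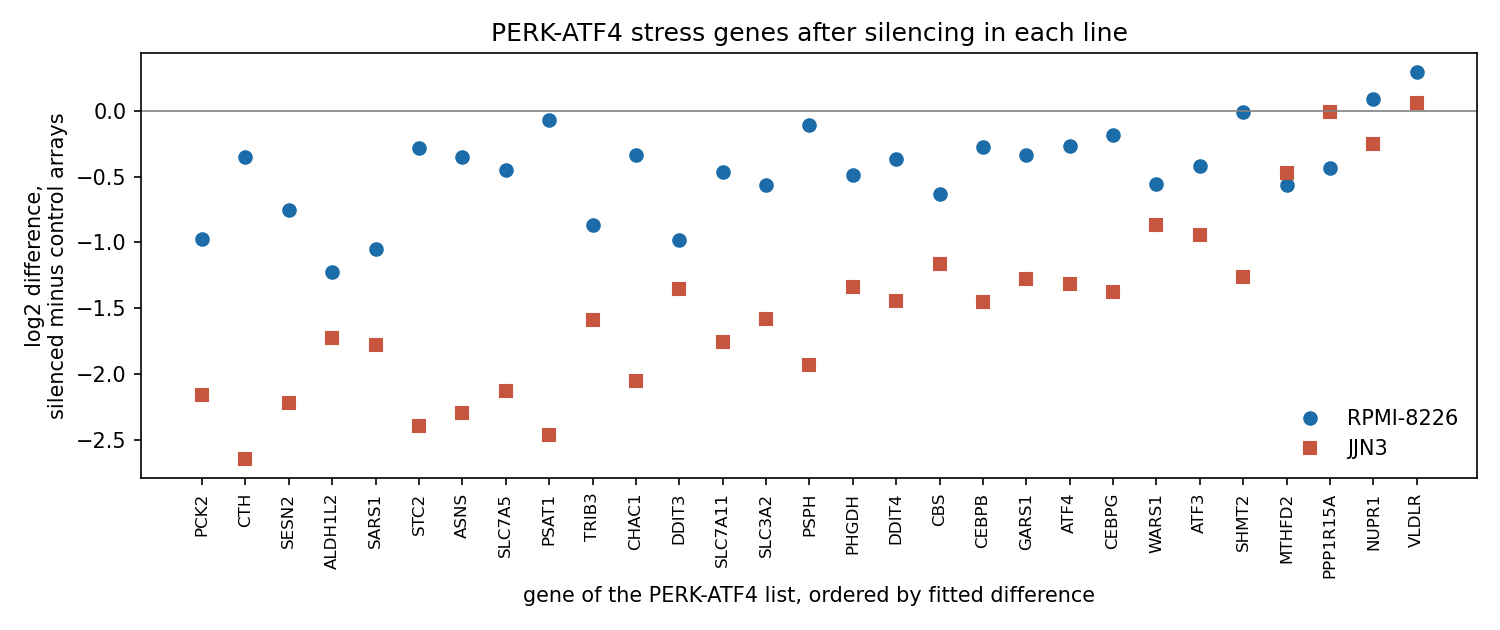
Log2 difference, silenced minus control, of the 29 PERK-ATF4 stress genes (vertical axis) in RPMI-8226 and JJN3, 1 point per gene and line. The list median was -0.42 in RPMI-8226 and -1.45 in JJN3.

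IRE1 shRNA against XBP1 shRNA asked whether the shRNAs gave different responses. Members of the MHC class II, plasma cell identity and NF-kB target lists rose with IRE1 shRNA relative to XBP1 shRNA, 2 of 12, 4 of 20 and 2 of 16 over all genes. After quantile normalisation 0, 0 and 2 passed with limma (2901 of all genes at an unadjusted p under 0.05), and after loess 2, 4 and 2. HLA-DRA and HLA-DPB1, whose probe sets can cross-hybridise, rose by 1.15 and 1.09; IRF4, PRDM1, the elongation factor ELL2 and the coactivator POU2AF1 rose by 1.18, 0.96, 0.95 and 0.82; and TNFAIP3, an NF-kB inhibitor, and the chemokine CXCL10 rose by 1.52 and 1.66. XIAP, BAD and MDM2, the p53 ubiquitin ligase, fell by 1.60, 0.82 and 0.82, and DNAJC3 fell by 1.28. Over all genes 317 genes rose and 340 fell, 657 in all and each with the same sign in both lines (3141 at an unadjusted p under 0.05; median size 1.0). The largest rises were HMGA1 (2.17), MARCKSL1 (2.10), CMAHP (2.01), MPI (1.83), TNFRSF1B, a TNF receptor (1.79), PTGER4, a prostaglandin receptor (1.78), USP14 (1.77), KIF1C (1.76), R3HDM1 (1.76), TMEM132D-AS1 (1.75), NFIA (1.74) and the protease CTSH (1.71). The largest falls were the histone genes H2BC12 (-3.19 ± 0.20) and H2BC12L (-2.57), the sodium pump subunit ATP1B1 (-2.32), RNF11 (-2.08), PCTP (-1.95), KIAA1191 (-1.94), STAU1 (-1.93), RPRD1A (-1.92), MXD1 (-1.90), TPRG1L (-1.84), MACROD1 (-1.83) and CAB39L (-1.77). With another choice of probe set 13 of these 24 genes shrank by more than 1.5 times. With that of highest mean R3HDM1 was at -0.27, KIF1C at -0.31, HMGA1 at 0.21, USP14 at 0.18, MXD1 at -0.0295 and MACROD1 at -0.0289, and with the mean of its probe sets RPRD1A was at -0.31. The poly-A control median was 0.43 and 0.19 on the XBP1 shRNA arrays and -0.03 and -0.10 on the IRE1 shRNA arrays, in RPMI-8226 and JJN3. The hybridisation control median of the JJN3 IRE1 shRNA array was 0.42. Of the calls here and in XBP1 shRNA against NT shRNA (657 and 436), 226 were shared, and all 226 had opposite signs, as XBP1 shRNA arrays enter both.

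Of the 12 MHC class II genes 2 rose over all genes and 9 adjusted over the list alone; the list median was 0.73 (0.38 in RPMI-8226, 1.21 in JJN3; adjusted p = 8.44e-08; adjusted p = 0.819 with an estimated correlation). MYC rose by 0.82, and 6 genes of its list rose adjusted over the list alone (median 0.28, adjusted p = 0.00260). Plasma cell identity (4 genes rose, median 0.21) and the stromal and epithelial list shifted up as well (median 0.18; both adjusted p = 0.0238); in the latter VIM, which plasma cells also express, rose by 0.89. These last 3 lists had an adjusted p = 0.819 with an estimated correlation. NF-kB targets (0.0617), the BCL2 family and p53 targets (both 0.162), XBP1-dependent secretory genes (0.330) and PERK-ATF4 genes (0.379; medians 0.36 in RPMI-8226 and -0.59 in JJN3) did not shift. The count of 657 was 10 without the JJN3 IRE1 shRNA array, 122 without RPMI-8226 IRE1 shRNA, 334 without JJN3 XBP1 shRNA, 371 without either NT shRNA array and 0 without the cell line block (411 at an unadjusted p under 0.05). The balance turned on single arrays here too: 190 rose and 337 fell without RPMI-8226 XBP1 shRNA, and 213 and 121 without JJN3 XBP1 shRNA. List calls ended without RPMI-8226 XBP1 shRNA (plasma cell identity, adjusted p = 0.155), RPMI-8226 IRE1 shRNA (plasma cell identity, 0.0825; MYC, 0.0510), JJN3 XBP1 shRNA (MYC and the stromal list, 0.217) and JJN3 IRE1 shRNA (stromal list, 0.0776). The MHC class II median was 0.48 without JJN3 IRE1 shRNA, and that of the stromal list 0.30 without RPMI-8226 XBP1 shRNA and 0.29 without RPMI-8226 IRE1 shRNA.

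NT shRNA against uninfected cells was the control for the response to lentivirus. The labels give polybrene for infected cells only, so virus, NT shRNA and polybrene cannot be told apart here. Genes of cholesterol synthesis shifted up (median 0.26, adjusted p = 8.65e-06; adjusted p = 0.772 with an estimated correlation): 18 of 20 were higher with NT shRNA, 15 of them in both lines. MSMO1, a sterol oxidase, rose adjusted over the list alone (0.99); HMGCS1, of the mevalonate pathway, was at 1.17 and INSIG1, a sterol sensor partner, at 0.79. Hypoxia and glycolysis genes shifted up (median 0.17, adjusted p = 0.00406), with the glucose transporter SLC2A3 at 1.05, and MHC class II (-0.27, 0.0120), PERK-ATF4 (-0.26, 0.0344) and S phase genes (-0.12, 0.0409) shifted down. Each of these lists had an adjusted p = 0.772 with an estimated correlation. Limma called 0 genes (1164 at an unadjusted p under 0.05, smallest adjusted p 0.784). By size in both lines, NUP58 (1.76), EMP1 (1.10), ZNF790-AS1 (1.02), OTUB2 (0.99), IGFBP3 (0.93), PGM2L1 (0.93), PXYLP1 (0.91) and ENDOD1 (0.90) stood highest, and RAC1 (-1.72), STAU1 (-1.33), TTC7B (-1.31), SSBP3 (-1.25), DPYSL2 (-1.12), BTBD7 (-1.11), GUCD1 (-1.08), FAM120A (-0.94), NUP35 (-0.93) and the cell cycle transcription factor MYBL2 (-0.86) lowest. The count was 3 without the JJN3 NT shRNA array and 0 without the cell line block (42 at an unadjusted p under 0.05). Without RPMI-8226 NT shRNA the adjusted p was 0.268 for PERK-ATF4 (median 0.18) and 0.689 for S phase (0.07); without JJN3 uninfected it was 0.856 for both (0.20 and 0.10) and for MHC class II; without JJN3 NT shRNA it was 0.810 for MHC class II and 0.793 for hypoxia, and without RPMI-8226 uninfected 0.0589 for hypoxia. Among calls that held, without RPMI-8226 uninfected the medians were -0.55 for PERK-ATF4, -0.42 for MHC class II, -0.26 for S phase and 0.13 for cholesterol synthesis. They were -0.58 for PERK-ATF4 and -0.29 for S phase without JJN3 NT shRNA, -0.50 for MHC class II and 0.28 for hypoxia without RPMI-8226 NT shRNA, and 0.47 for cholesterol synthesis without JJN3 uninfected.

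The interaction asked where arrays labelled with an shRNA against XBP1 or IRE1 differed from control by other amounts in the lines. The replicates of a line were here its 2 shRNAs and its 2 controls, not repeated cultures of 1 treatment. XBP1 stood at 61.6% of control in RPMI-8226 and 28.5% in JJN3. That difference between the lines did not pass in limma, at -1.11 ± 0.55 (adjusted p = 0.991 over all genes and 0.152 over the targets alone). With 242021_at it was 0.0605. ERN1 stood at 48.5% and 47.0% over both shRNAs, and at 129.8% of NT shRNA on the RPMI-8226 IRE1 shRNA array. PERK-ATF4 genes were lower after silencing in JJN3 than in RPMI-8226: the serine synthesis enzymes PSAT1 (-2.39) and PSPH (-1.82), the transsulfuration enzyme CTH (-2.29) and STC2, a secreted glycoprotein (-2.11), were among 9 that fell adjusted over the list alone, with a list median of -1.05 (adjusted p = 3.90e-18; adjusted p = 0.524 with an estimated correlation). S phase genes shifted down too (median -0.59, adjusted p = 4.16e-14; adjusted p = 0.232 with an estimated correlation), the helicase subunits MCM4 (-1.0) and MCM10 (-0.90) and CHAF1B falling adjusted over the list alone. Interferon response genes shifted up (median 0.28, adjusted p = 6.59e-05; adjusted p = 0.232 with an estimated correlation), with IFIT3 at 2.22, PARP9 at 1.81, IFITM1 at 1.16 and IFIT5 at 1.15; PARP9 was at -0.36 after cyclic loess. G2 and mitosis (-0.31, 0.00165), MYC (-0.24, 0.00525) and hypoxia genes (-0.28, 0.00525) shifted down, each with adjusted p = 0.736 with an estimated correlation. Limma called 0 genes (943 at an unadjusted p under 0.05; smallest adjusted p 0.336, reached by PRAG1, PSAT1, STC2 and CDC14B). Other named genes, none past the threshold, were IL10, an interleukin (3.32, from -3.37 in RPMI-8226 and -0.05 in JJN3; adjusted p = 0.991), PRAG1 (2.18), DIS3L2 (2.14), CHRNA1 (1.91), TGIF1 (1.85), SCN9A (1.84), SOCS3 (1.74, but -0.53 after cyclic loess) and TP53INP1 (1.70), and, in the other direction, LRATD2 (-2.41), INHBE (-2.10), CDC14B (-2.09), MAP1B (-2.05), JDP2 (-2.04), asparagine synthetase ASNS (-1.94) and CLIC5 (-1.93). The count was 2 without the RPMI-8226 uninfected array. Without single arrays the adjusted p of G2 and mitosis was 0.117 (RPMI-8226 NT shRNA) and 0.121 (JJN3 XBP1 shRNA), that of MYC 0.262 (RPMI-8226 IRE1 shRNA), 0.0655 (JJN3 NT shRNA) and 0.384 (JJN3 XBP1 shRNA), and that of hypoxia 0.182 (RPMI-8226 uninfected), 0.208 (RPMI-8226 IRE1 shRNA), 0.347 (JJN3 NT shRNA) and 0.143 (JJN3 IRE1 shRNA). Without JJN3 IRE1 shRNA the medians were -0.60 for PERK-ATF4 and -0.40 for MYC, and without RPMI-8226 XBP1 shRNA that of G2 and mitosis was -0.20.

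JJN3 against RPMI-8226, over all treatments, compared the cultures of the lines. CTHRC1, a secreted matrix protein, was higher in JJN3 by 10.01 ± 0.14 on the log2 scale, and the growth factor HGF by 8.31, the collagen hydroxylase PLOD2 by 8.29, SKAP2 by 7.84, FABP5 by 7.74, FRMD6 by 7.44, the connexin GJA1 by 7.41, BCHE by 7.40, FZD6 by 7.38, SDC2 by 7.32, RFLNB by 7.26 and HLA-DQB1 by 7.19. IGLC1, an immunoglobulin light chain gene whose probe sets can cross-hybridise, was lower (-9.96 ± 0.16), as were fibronectin FN1 (-8.91), S100A4 (-8.23), IGLV1-44 (-7.96), the chemokine receptor CCR2 (-7.89), HAVCR2 (-7.74), EVI2B (-7.31), KISS1R (-7.12), MARCKS (-7.11), the chemokine CCL5 (-7.07), PAGE1 (-7.04) and IGFBP3 (-6.96). The sizes depended on the probe set: with another choice 10 of 25 genes, these 24 and ERN1, shrank by more than 1.5 times. With that of highest mean IGLC1 was at -0.72, IGLV1-44 at -0.58, FN1 at -1.61 and SKAP2 at 0.49. Of the 8 immunoglobulin genes IGKC was higher (2.70) and 7 were lower, JCHAIN at -2.12; after quantile or loess normalisation 5 passed as lower, and the list did not shift (camera adjusted p = 0.168). G2 and mitosis genes were higher in JJN3 (22 higher, 2 lower, median 0.97, adjusted p = 5.86e-07; UBE2C 4.91, CENPE 2.72), as were MHC class II (8 higher, 2 lower, median 0.79, adjusted p = 0.00312; HLA-DQA1 6.95, CD74 -0.63) and S phase genes (17 higher, 3 lower, median 0.56, adjusted p = 0.00394; CCNE2 2.63, MCM4 2.14); each had adjusted p = 0.997 with an estimated correlation. Of the plasma cell identity genes 6 were higher, ELL2 (2.05), IRF4 (1.70) and PRDM1 (1.67) among them, and 10 lower, with CD38 at -4.72; of the B cell genes 5 were higher (ETS1 3.57, BCL6 3.45) and 16 lower (BTK -3.59, CD53 -3.50). KRT18, an epithelial keratin, was lower (-5.37) and VIM higher (2.56). ERN1 was lower (-2.58, adjusted p = 1.22e-05) and XBP1 at 0.40 (0.210); with 242021_at XBP1 passed in the other direction, at -0.43 (adjusted p = 0.00586 over all probe sets). In all 13632 of 19775 genes passed, 5030 higher and 8602 lower, with a median over all genes of -0.23 (-0.17 after quantile and -0.11 after loess normalisation), so that single differences stand relative to that shift; 14294 had an unadjusted p under 0.05. Choosing the probe set of highest SD over these 8 arrays favours those that differ between the lines. With the probe set of highest mean 11735 genes passed in limma. The arrays of a line come from 1 line each, so the lines stand for these cultures alone.

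Without a test, 154 genes differed at least 2-fold the same way in both lines for XBP1 shRNA against NT shRNA (52 higher, 102 lower), 39 for IRE1 shRNA against NT shRNA (13 and 26), 203 for IRE1 against XBP1 shRNA (100 and 103) and 18 for silenced against control (2 and 16), where NT shRNA against uninfected cells gave 1. Across the 19775 genes, XBP1 shRNA minus NT shRNA in RPMI-8226 and in JJN3 correlated with r = 0.367, IRE1 shRNA minus NT shRNA with r = 0.253 and NT shRNA minus uninfected with r = 0.195 (Pearson). Across shRNAs and lines r was 0.106 (XBP1 shRNA in RPMI-8226 with IRE1 shRNA in JJN3) and 0.0136 (the converse). XBP1 shRNA against NT shRNA and IRE1 shRNA against uninfected cells gave r = 0.134 in RPMI-8226 and 0.262 in JJN3. IRE1 minus XBP1 shRNA gave r = 0.448 between the lines. Against the same NT shRNA array the shRNAs correlated with r = 0.480 in RPMI-8226 and 0.395 in JJN3, where noise alone gave 0.50 in simulation; the covariance was 0.0654 and 0.0630 against a simulated 0.0365. Of the genes called for both shRNAs against NT shRNA, DCP2 was shared among those that rose (190 and 3 genes; 0.0288 expected) and 0 among those that fell (246 and 9; 0.112 expected). RNF11 was called in opposite directions, higher with XBP1 shRNA and lower with IRE1 shRNA (0.124 such genes expected). The expected numbers leave out that both comparisons use the same NT shRNA arrays, so part of any excess may come from these. Simulated noise shared 0.12 genes on average, but with 0.54 calls a run for XBP1 shRNA it is no measure for lists of this length. Limma gave 3130 and 2090 genes at an unadjusted p under 0.05 in these comparisons.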

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

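The tests of the target genes, of the numbers of genes called and of the PERK-ATF4 list against the spread of all genes were chosen after the result was seen; the leave-out test of that list, its level in the control arrays and the splits of the arrays were not. Between the lines, 6 lists differed in their response to silencing (camera, JJN3 minus RPMI-8226): PERK-ATF4 genes (adjusted p = 3.90e-18), interferon response (6.59e-05), S phase (4.16e-14), G2 and mitosis (0.00165), MYC and ribosome biogenesis (0.00525) and hypoxia and glycolysis (0.00525). With an estimated correlation the adjusted p was 0.524 for PERK-ATF4, 0.232 for interferon response and S phase and 0.736 for the others. ERN1 with IRE1 shRNA moved in opposite directions in the lines, 0.376 in RPMI-8226 and -0.892 in JJN3 on the log2 scale against NT shRNA, a difference that was not tested. Both values lay within 2 SE of 0 (SE 0.464 per line), and against uninfected cells they were -0.64 and -0.96. Among 13522 probe sets without a single gene symbol, array control probe sets not counted, which the comparisons of genes leave out, 77 passed for XBP1 shRNA against NT shRNA (38 higher, 39 lower) and 109 for IRE1 against XBP1 shRNA (55 and 54), where NT shRNA against uninfected cells gave 0 with limma. The hybridisation control median of the JJN3 IRE1 shRNA array, 0.42, lay apart from the other 3 JJN3 arrays (gap over range 0.876); the critical value of Dixon's test, which set this limit, is by its construction passed by chance in about 1 of 20 groups.

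XBP1 and ERN1 were each lower on the arrays labelled with the shRNA against the other gene. An exchange of the XBP1 and IRE1 shRNA labels in a single line is argued against by the correlation of IRE1 minus XBP1 shRNA between the lines (r = 0.448), which such an exchange would make negative. A low ERN1 signal on the NT shRNA array of RPMI-8226 cannot be the whole cause, because IRE1 minus XBP1 shRNA, which uses no NT array, was 1.82 in that line (SE 0.464). An exchange of the labels in both lines and shRNAs that act as labelled cannot be told apart. With the chosen probe sets 4 of the 4 differences had the sign of an exchange. Of these, 2 lay beyond 2 SE, and that of XBP1 in RPMI-8226 was -0.0254. In RPMI-8226 and JJN3, ERN1 227755_at gave 1.58 and 0.22, with that sign. XBP1 242021_at gave 0.19 and 0.0696, against it, and ERN1 207061_at gave -0.0390 and 0.21. Over all arrays these last 2 probe sets ran only from -0.23 to 0.33 and from -0.25 to 0.21. In the joint fit their differences between the shRNAs were 0.13 ± 0.14 and 0.084 ± 0.15, each smaller than its SE. They are therefore no evidence for or against an exchange. The expression of each gene may also answer to loss of the other, a biological explanation that was not tested.

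More genes passed on the arrays labelled XBP1 shRNA than on those labelled IRE1 shRNA. The NT shRNA array of RPMI-8226, without which 0 genes passed for XBP1 shRNA (limma; 2307 at an unadjusted p under 0.05), is not the whole cause, since uninfected cells as control gave 686 genes for XBP1 shRNA and 4 for IRE1 shRNA. Independent noise of single arrays is argued against as the whole source of the XBP1 shRNA differences by their correlation between the lines (r = 0.367). IRE1 shRNA minus NT shRNA gave r = 0.253 with 12 genes called, and NT shRNA minus uninfected gave 0.195 with 0 genes in limma. So the correlation does not decide why the counts differ between the shRNAs. RNA labelling that differed on the XBP1 shRNA arrays and a wider response to that shRNA cannot be told apart: the poly-A control median of these arrays lay above the next highest array of the line by 0.173 in RPMI-8226 and 0.239 in JJN3, too little to decide, and each treatment had 1 array per line. The difference between the shRNAs in XBP1 and ERN1 could also bear on it, and that was not tested beyond the values above.

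PERK-ATF4 stress genes were lower after silencing in JJN3 than in RPMI-8226. Wider changes of all genes in JJN3 are argued against: divided by the SD of all genes the list median was 2.87 times as large in JJN3, and 27 of 29 members were lower there on that scale. A single array is argued against as the whole cause, because the highest camera adjusted p with any 1 array left out was 1.19e-09 at the preset correlation (0.524 with an estimated correlation and no array left out), although without JJN3 IRE1 shRNA the median of the difference moved from -1.05 to -0.60. A higher level of these genes in the JJN3 controls may contribute and stays open: the list median, JJN3 minus RPMI-8226, was 0.41 in the control arrays (0.409, with 18 of 29 members higher) and -0.63 in the silenced arrays (8 of 29), against all-gene medians of -0.19 and -0.25. Over both shRNAs and both controls XBP1 stood at 61.6% of control in RPMI-8226 and 28.5% in JJN3, a difference that did not pass. ERN1 stood at 48.5% and 47.0%. These means leave out unequal levels with IRE1 shRNA, where the list medians against NT shRNA were -0.14 and -1.85. There XBP1 stood at 64.7% and 16.8% of NT shRNA, and ERN1 at 129.8% and 53.9%. Against uninfected cells ERN1 with IRE1 shRNA stood at 64.1% and 51.6%. An unequal depth of silencing was not tested as a cause. Nor was a different reliance of the lines on this stress response, a biological explanation.

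Other splits of the arrays were fitted for 3 of the gene counts. For silenced against control, 34 of the 34 splits into 4 and 4 that the block allows gave as many genes as the real one (0 genes with limma; highest other 0), which a count of 0 makes certain and which therefore decides nothing; the real split had 1992 genes at an unadjusted p under 0.05 and the highest other 2088. For JJN3 against RPMI-8226, the 8 splits that part the 2 arrays of every treatment, a restriction made after the counts were seen, are too few for a share under 0.05; the real one gave 13632 genes and the highest other 0, and every other split leaves the difference between the lines in the error. For the interaction, 18 splits within the lines are too few for a share under 0.05; the real value was 0 (limma; 943 at an unadjusted p under 0.05) and the highest other 7, from the split that sums the silencing effects of the lines.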

How the results depend on the processing

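The filter to the probe sets above the median SD, the probe set of highest mean and, for the lists, the mean of probe sets, the SD filter and cyclic loess were chosen after the data were seen. Centred values hold no signal over background, so no filter on dim probe sets could be made. Of 136 alternative counts of genes 79 stayed within 1.5 times of the count reported, 22 were higher and 35 lower; of 702 list medians 535 kept direction and call, 162 lost the call and 5 turned. Of 3029 values of named genes 2636 kept both, and of 129 target values 117. Of the other target values 8 turned and 4 gained the call. With no replicate block, so that the cell lines are not paired, limma gave 0 genes for XBP1 shRNA, IRE1 shRNA and IRE1 against XBP1 shRNA (381, 180 and 411 at an unadjusted p under 0.05) and 12877 for the lines, and 2 lists for IRE1 against XBP1 shRNA; leaving out the block puts the difference between the lines into the error.

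For XBP1 shRNA against NT shRNA (436 reported) the count was 161 with the 60th percentile filter, 275 with the mean of probe sets, 659 with all probe sets, 871 with a trend and robust variances, 970 at a threshold of 0.1, 221 with the probe set of highest mean and 686 against uninfected cells. For IRE1 shRNA against NT shRNA (12) it was 1 with the 60th percentile filter, 5 with the mean of probe sets, 286 with the trend, 1 after quantile and 0 after loess normalisation (limma; 2086 at an unadjusted p under 0.05), 46 at 0.1, 4 with the SD filter, 2 with the probe set of highest mean and 4 against uninfected cells. For silenced against control (0; limma, 1992 at an unadjusted p under 0.05) it was 48 with the trend, 11 after quantile normalisation, 5 at 0.1 and 25 with NT shRNA as the sole control. For IRE1 against XBP1 shRNA (657) it was 340 with the 60th percentile filter, 297 with the mean of probe sets, 1034 with all probe sets, 1158 with the trend, 369 after quantile normalisation, 1239 at 0.1 and 395 with the probe set of highest mean. NT shRNA against uninfected cells gave 5 with the trend, and the lines gave 7337 with the 60th percentile filter and 30636 with all probe sets. The filter tests fewer genes and also puts other probe sets in place, and the uncollapsed table tests more; the cause was not tested for any setting. With 1 array left out the counts ran from 0 to 350 for XBP1 shRNA, 0 to 32 for IRE1 shRNA, 0 to 40 for silenced against control, 10 to 527 for IRE1 against XBP1 shRNA, 0 to 3 for NT shRNA against uninfected, 0 to 2 for the interaction and 11904 to 12207 for the lines.

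ERN1 with XBP1 shRNA passed at a threshold of 0.1 (-1.33) and against uninfected cells (-1.88), was -0.0746 with 207061_at, and with 1 array left out ran from -1.82 to -0.85. XBP1 with XBP1 shRNA ran from -1.32 to -0.41, and was -0.0834 with 242021_at. XBP1 with IRE1 shRNA ran from -2.45 to -0.76, and was 0.0478 with the 60th percentile filter and the probe set of highest mean, where 242021_at stands for the gene. ERN1 with IRE1 shRNA ran from -0.77 to 0.26, with 0.07 without JJN3 NT shRNA and 0.26 without JJN3 IRE1 shRNA; it was 0.0636 after loess normalisation and 0.0093 with 207061_at, which gave 0.0204 for silenced against control.

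The lists shifted in number as follows. With an estimated correlation 0 lists passed in all 7 comparisons; with fry 0 passed for both shRNAs against NT shRNA, IRE1 against XBP1 shRNA, NT shRNA against uninfected and the interaction, 2 for silenced against control and 12 for the lines. IRE1 against XBP1 shRNA had 2 with the SD filter, and NT shRNA against uninfected 3 with the SD filter and 3 after loess normalisation; with 1 array left out these counts ran from 3 to 7 and from 2 to 7. PERK-ATF4 and S phase medians of NT shRNA against uninfected turned to 0.18 and 0.07 without RPMI-8226 NT shRNA and to 0.20 and 0.10 without JJN3 uninfected, the lowest being -0.58 and -0.29, and the cholesterol median of IRE1 shRNA was 0.0663 against uninfected cells. Counts at 1.5-fold in both lines were 817, 387, 216, 935 and 62 for XBP1 shRNA, IRE1 shRNA, silenced against control, IRE1 against XBP1 shRNA and NT shRNA against uninfected; loess normalisation gave 2 at 2-fold for the last.

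Among named genes these signs turned, the 60th percentile filter and the highest mean putting another probe set in place: DCP2 was -0.63 with XBP1 shRNA, -0.0209 with IRE1 shRNA and -0.22 for silenced against control, TMED4 -0.49 with IRE1 shRNA, ADCY1 0.0288 for silenced against control, R3HDM1 -0.27 and XBP1 0.13 for IRE1 against XBP1 shRNA, XBP1 0.0136 for NT shRNA against uninfected, SOCS3 -0.22 and XBP1 0.0605 in the interaction and XBP1 -0.43 between the lines. With the highest mean alone PLBD2 was 0.12 with XBP1 shRNA and KIF1C -0.31 for IRE1 against XBP1 shRNA. With the mean of probe sets RPRD1A was -0.21 with XBP1 shRNA and XBP1 -0.0135 between the lines. After loess normalisation the interaction was -0.53 for SOCS3, -0.36 for PARP9 and 0.48 for ERN1; the cause was not tested. With 1 array left out XBP1 ran from -1.58 to 0.11 for IRE1 against XBP1 shRNA, the highest without JJN3 IRE1 shRNA; for NT shRNA against uninfected the lowest was -0.50, and the sign turned to 0.42 without RPMI-8226 NT shRNA and 0.24 without JJN3 uninfected. The ERN1 interaction, at the lowest -0.96, was 0.47 without RPMI-8226 NT shRNA, 0.87 without RPMI-8226 IRE1 shRNA and 0.12 without JJN3 XBP1 shRNA.

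Correlations across genes moved as follows, in the order loess, 60th percentile filter and SD filter: XBP1 shRNA between the lines 0.351, 0.329 and 0.409, and XBP1 shRNA in RPMI-8226 with IRE1 shRNA in JJN3 0.0782, 0.0897 and 0.123. With the 60th percentile and SD filters IRE1 shRNA between the lines had 0.226 and 0.291, IRE1 minus XBP1 shRNA 0.415 and 0.487, and NT shRNA minus uninfected 0.170 and 0.230; with the SD filter XBP1 shRNA against NT shRNA and IRE1 shRNA against uninfected had 0.152 in RPMI-8226 and 0.283 in JJN3. The cause was not tested.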

Other observations

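The histone class was tested after its members had been seen among the named genes, with the test written before its result was known. Other values here were looked up after the data were seen. The histone p values were not adjusted over comparisons or gene sets, whereas those of the gene lists were adjusted. They therefore cannot be set beside the adjusted p of those lists. With the named histone genes included, the tests also hold the members for which the class was picked. Histone genes, which package DNA and are expressed with S phase, were lower with IRE1 shRNA than with XBP1 shRNA. Of 45 measured histone genes 9 fell and 36 had negative differences, with a median of -0.22; after quantile and loess normalisation 36 of 45 were negative as well, and 8 and 9 fell. Against NT shRNA, 5 rose with XBP1 shRNA (2 after quantile normalisation) and 32 of 45 were higher, with a median of 0.28. The unadjusted p was 0.0498 with an estimated correlation (limma camera). Without the named histone genes it was 0.0602 with an estimated correlation. With IRE1 shRNA against NT shRNA the median was -0.05, with 19 higher and 26 lower and 1 that fell, H2BC12 (camera p = 0.0470, and p = 0.278 with an estimated correlation; 0.123 and 0.340 without the named ones). Without the 3 of these 45 already named, H2AC8, H2BC12 and H2BC21 (H2BC12L is not among the 45), the remaining 42 had a median of -0.21 between the shRNAs, 33 of them lower (camera p = 1.04e-06, and p = 0.0371 with an estimated correlation). In the joint fit of both lines S phase genes did not move with the histone genes. Their list median was 0.12 for IRE1 minus XBP1 shRNA, with 20 of 31 higher. For XBP1 shRNA against NT shRNA it was -0.13, with 20 of 31 lower. The lines differed in sign there, with S phase medians of 0.25 in RPMI-8226 and -0.50 in JJN3. Histone medians were not computed per line, so the comparison within a line was not made. The poly-A control medians were 0.43 in RPMI-8226 and 0.19 in JJN3 with XBP1 shRNA, and -0.03 and -0.10 with IRE1 shRNA. A candidate explanation is a change of the whole histone class that separates the shRNAs. A difference in RNA labelling between these arrays cannot be told apart from it. Histone genes are close paralogs whose probe sets may cross-hybridise, which was not tested.

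The S phase list median after silencing was 0.15 in RPMI-8226 and -0.46 in JJN3. The list passed in the interaction at the preset correlation (adjusted p = 4.16e-14) but not with an estimated correlation (adjusted p = 0.232) or with fry, and 0 members passed over all genes with limma (943 of all genes had an unadjusted p under 0.05). In the interaction 31 of 31 members were lower after quantile and 30 of 31 after loess normalisation. The reported IRE1 RNase decay targets, 9 genes whose mRNA IRE1 has been reported to cleave, shifted in neither shRNA comparison, with BLOC1S1, the best known of them, at 0.06 for silenced against control. Markers of T and NK cells, myeloid cells and erythroid cells did not shift with silencing (camera adjusted p 0.509, 0.681 and 0.586). Nor did B cell genes (0.868), immunoglobulin genes (0.549) or NF-kB targets (0.837).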
